A study of Mus musculus with 18 samples.

How the data were processed

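The series measured gene expression in bone-marrow-derived macrophages of IL-10-deficient mice, cultured for 7 days in medium with CSF-1 and then treated for 10, 20 or 30 min with LPS at 100 ng/ml, alone or together with 10 ng/ml of IL-10. Per the labels' protocols, total RNA was extracted with Trizol, biotin-labelled cRNA was prepared by the standard Affymetrix procedure, and each replicate number is a complete independent experiment. The data were 18 single-colour arrays with 45101 probe sets each, of which 64 were control probe sets. The deposited values are intensities on a linear scale, 1 column per array, processed with GCOS 1.4 per the submitters' processing notes. The signal algorithm and its settings are not given in the sources used here. In the deposited intensities the mean signal after trimming 2 percent of probe sets at each end was close to 500 on every array, which is the scaling the values arrived with. No detection calls were used here, so a low signal cannot be told from background, and the scaling makes a change of total RNA per cell invisible. Array precision was limited by the number of arrays, 3 per group.

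Probe sets were named from the platform annotation, which can be old: 34958 carried 1 gene symbol, 932 several and 9211 none, and those with several or none were left unnamed. No symbol was changed on matching to the gene table. Samples were grouped by treatment and time from their labels, 6 groups of 3 arrays. No pair of arrays held the same values: at most 104 probe sets were equal in any of the 153 pairs.

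Signals were turned into log2(signal + 16), so fold changes of dim probe sets are understated. A probe set was tested if its signal reached the array's median on at least 3 arrays. This left 27110 probe sets, and 12527 genes with a representative probe set, the one with the highest mean log2 signal. The linear model of limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) was fitted to all 18 arrays with 1 coefficient per group, which left 12 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. There were 10 comparisons: IL-10 plus LPS against LPS at 10, 20 and 30 min and averaged over the times, 20 and 30 against 10 min under each treatment, and the change of the IL-10 effect from 10 to 20 and from 10 to 30 min. Means and SDs are given on the signal scale, fold changes and SEs on the log2(signal + 16) scale.

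The labels make the replicate number an experiment of its own, so whether the numbers pair the samples was checked in the data. The deviations from the group means correlated at 0.20 to 0.64 (median 0.46) in the 45 pairs of arrays with the same number in different groups, and at -0.47 to 0.0651 in the 90 pairs with different numbers. All 18 arrays correlated best with an array of their own number. The first 2 principal components of the arrays took 30.4 and 13.4 percent of the variance. The numbers therefore pair the samples, and values from the fit with the replicate block (10 residual degrees of freedom) stand beside results whose call or count they change. The fit chosen as the main one has no block. It counts the differences between experiments as spread, so its p-values tend to be too large.

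Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 19 lists of a comparison, and with an estimated correlation beside it. The lists were immediate early regulators, NF-kB pathway feedback, inflammatory cytokines and chemokines, IL-10 and STAT3 induced genes, MAPK and mRNA decay feedback, interferon response, TLR4 and IL-10 receptor signalling, heat shock and unfolded protein, Kruppel-like factors and transcription repressors, serum response and cytoskeleton, housekeeping, and cell cycle. Markers of macrophages, granulocytes, B and T lymphocytes, erythroid cells, stromal cells and dendritic cells and sex-linked genes made up the rest. Of the 270 genes in the lists 226 had a tested probe set. The least covered were the inflammatory list (14 of 22), the lymphocyte (3 of 12) and erythroid markers (2 of 8) and the sex-linked list (1 of 5).

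The genes named follow a rule set before the data were examined, as were the tests, the lists and the other settings below except where said. Per comparison these are up to 10 genes in each direction with the largest fold change among called probe sets with 1 symbol and the same sign in all 3 experiments (8 of 9 pairs for the average), the same from the blocked fit, up to 4 members of each list and any called member, and a fixed panel of signalling, cytokine and feedback genes. A gene is given by its representative probe set unless another of its probe sets passed, and then that is said.

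Other settings tried were quantile normalisation, pseudocounts of 1 and 64, no filter and a filter at the 75th percentile (11259 probe sets), the replicate block, a fit on only the arrays of the groups compared, no intensity trend, and leaving out each experiment. Leaving out the LPS arrays of experiments 2 and 3 at 20 min, which stood apart from the others, was added after seeing the data, as was leaving out experiments or these arrays within the blocked fit. The fit was tested on simulated data for the IL-10 comparison at 30 min, with 200 of the 27110 probe sets changed by known amounts. The 200 were drawn from probe sets with a mean log2 signal above 8. Without the block it called 1.49 percent of probe sets changed 1.5-fold, 29.9 percent of those changed 2-fold and 80.3 percent of those changed 4-fold, and with the block 37.3, 79.1 and 98.5 percent. Of the 26910 unchanged probe sets it called 1 and 3. The simulated noise was normal and independent between probe sets, with no arrays that stand apart. These rates therefore need not hold for dimmer probe sets or for the real arrays. Benjamini-Hochberg adjustment is also milder when many probe sets change, so with fewer than 200 changed the rates would be lower. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.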

Results

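Macrophages grown for 7 days from the bone marrow of mice without a working Il10 gene were given LPS at 100 ng/ml, the bacterial product that activates Toll-like receptor 4, or LPS together with IL-10 at 10 ng/ml, a cytokine that restrains macrophage activation through the transcription factor STAT3. RNA was taken after 10, 20 or 30 min, and 18 Affymetrix arrays were run, 3 for each of the 6 combinations of treatment and time. The 3 arrays of a group came from 3 independent experiments, called experiments 1, 2 and 3 here, done one after the other with mice of the same age and sex. The series title names a transcriptional repressor and a co-repressor that STAT3 signalling induces. Etv3 and Sbno2 were in the panel of genes named in every comparison because the study is known to be about them, and they are not independent evidence. Etv3 had 4 tested probe sets, and the third-brightest is named where it passed. Untreated cells were not analysed here, so every value compares 2 time points or 2 treatments.

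Every array had a trimmed mean signal near 500 (from 499.81 to 499.84), and the median signal lay between 75.6 and 120.9. The number of arrays, 3 per group, limits the precision of each value. The targeted gene, Il10, gave a signal on all 18 arrays, from 602 to 3209, above each array's median. No wild-type arrays were analysed here and the position of the probes relative to the disruption is not given in the sources used here, so this signal checks nothing about the genotype. The LPS arrays of experiments 2 and 3 at 20 min stood apart from the other 16. Their lower quartiles of signal were 38.6 and 34.0, against 21.8 to 31.0 on the others, and their median Spearman correlations with the remaining arrays were 0.921 and 0.908, against 0.925 to 0.943. Their 3' to 5' signal ratios for Gapdh were 0.873 and 0.906, inside the range of the other arrays (0.762 to 1.02), and those for Actb were 1.18 and 1.34, against 1.12 to 1.33.

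With LPS alone, chemokine and feedback genes rose between 10 and 30 min. Without untreated cells this rise with time cannot be tied to LPS itself. Cxcl2, a neutrophil chemokine, rose from 3628 ± 1210 to 19557 ± 3113 (mean signal ± SD, n = 3; log2 fold change 2.46, SE 0.27, limma adjusted p = 0.00243). Dusp1, the phosphatase that switches off MAP kinases, rose from 4208 ± 1064 to 13908 ± 2916 (log2 fold change 1.73, SE 0.23), and the stress-response gene Ier3 rose from 2886 ± 785 to 8460.2 ± 1642 (1.56, SE 0.19). The cAMP phosphodiesterase gene Pde4b rose by 1.71 (SE 0.27) and Socs3, an inhibitor of cytokine signalling, by 1.87 (SE 0.30) on the log2 scale, both at an adjusted p of 0.0496. These 5 probe sets of 5 genes were the calls of the fit without a block, and none fell. With the experiment as a block, 29 probe sets of 21 genes rose and 1 fell.

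The block added more inflammatory genes to the risers with LPS alone at 30 min. Cxcl1, another neutrophil chemokine, went from 367 ± 92.8 to 4151 ± 2744 (log2 fold change 3.28, blocked SE 0.27, blocked adjusted p = 3.27e-06), and Tnf, the gene of the cytokine TNF, from 1643 ± 1423 to 6586 ± 3804 (2.26, blocked SE 0.23, blocked adjusted p = 6.70e-05). Ptgs2, which encodes the inducible cyclooxygenase, rose by 1.90, the signalling adaptor gene Traf1 by 1.74, the cytokine gene Tnfsf9 by 1.52 and the chemokine gene Ccl3 by 1.05 on the log2 scale. Zfp36, which encodes an mRNA decay factor, rose by 1.13, Nfkbiz, a nuclear regulator of NF-kB target genes, by 1.06 and Tnfaip3, an inhibitor of NF-kB signalling, by 0.88 with the block. The immediate early genes Ier2 (1.46), Ppp1r15a (1.03) and Btg2 (not its brightest probe set, 1.39) and the phosphatase gene Dusp5 (1.36) rose as well. The long noncoding RNA Neat1 was the 1 probe set that fell, from 5178 ± 758 to 2964 ± 765 (log2 fold change -0.83, blocked adjusted p = 0.0155). Il1b (log2 fold change 1.55, blocked adjusted p = 0.0857), Egr1 (2.34), Fos (0.76), Junb (0.76) and Nfkbia (0.03) passed neither fit. Sbno2 (-0.17) and the brightest probe set of Etv3 (0.10) did not pass either. Leaving out experiment 1, 2 or 3 left 2, 0 and 2 calls without the block, and 8, 10 and 32 with it.

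**Figure D1:**
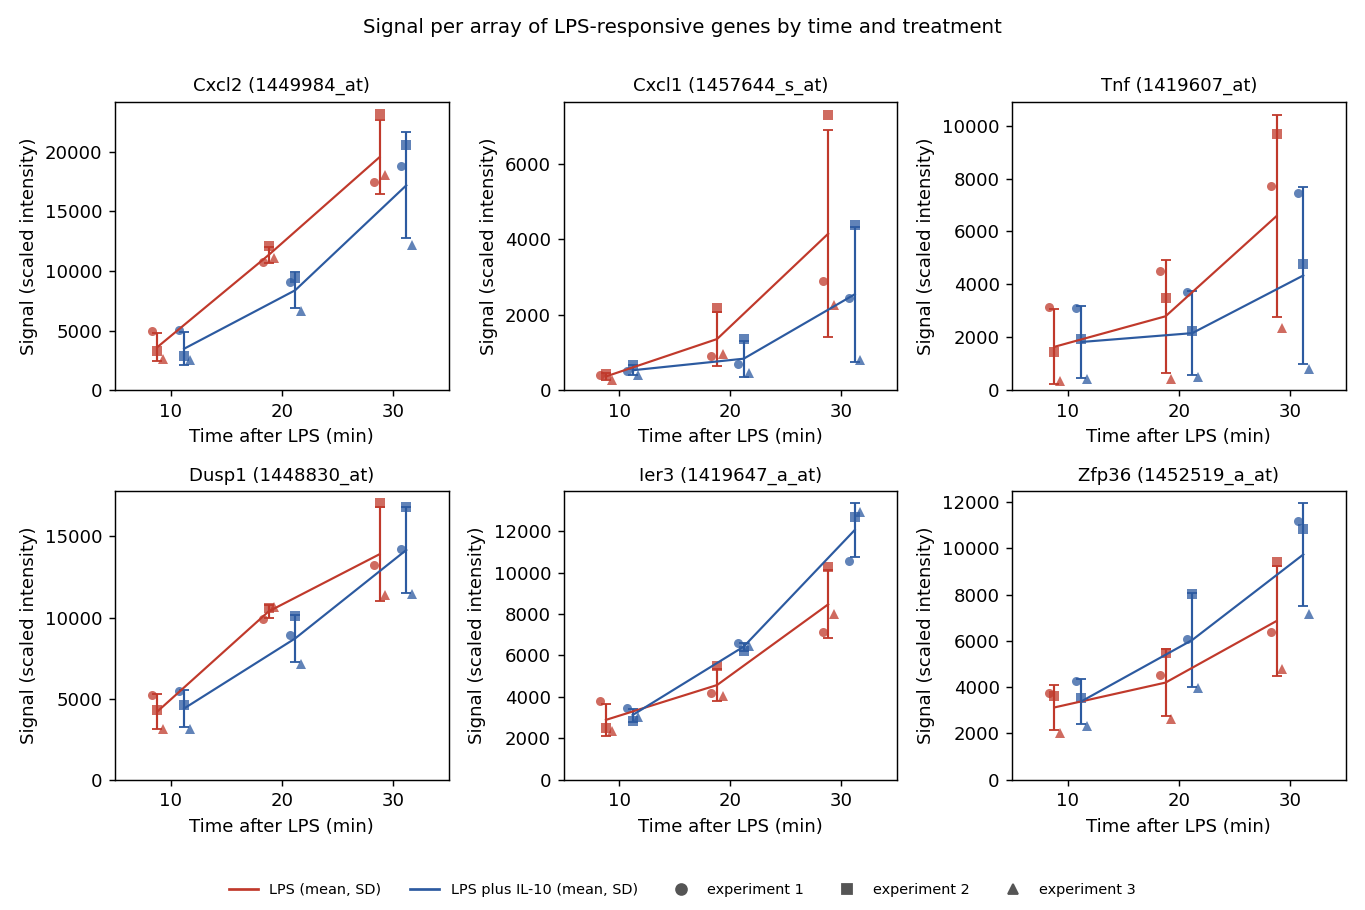
Scaled signal (vertical axis, linear) of 6 LPS-responsive genes against time after LPS in minutes, for LPS alone (red) and LPS plus IL-10 (blue), with 1 symbol per array shaped by experiment, lines joining group means and bars for SD (n = 3). Cxcl2 rose with time under both treatments, and Tnf was lowest in experiment 3 in each of the 6 groups.

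Several of the gene lists fixed beforehand shifted upwards with LPS between 10 and 30 min. Of the inflammatory cytokines and chemokines, 12 of 14 measured members had higher values at 30 min (median log2 fold change 1.11, camera adjusted p = 2.7e-20, 0.0016 with an estimated correlation). Over all probe sets 1 representative member rose without the block and 6 with it, and 5 and 10 rose when adjusted over the list alone. Of the immediate early regulators 22 of 24 were higher (median 0.51, adjusted p = 2.4e-18, 0.013 with an estimated correlation), with Ier3 called without the block. Of the MAPK and mRNA decay feedback genes 13 of 17 were higher (median 0.24, adjusted p = 7.1e-08, 0.0016 with an estimated correlation), led by Dusp1 and Dusp5. All 15 measured NF-kB pathway feedback genes were higher (median 0.33, adjusted p = 1.5e-06, 0.049 with an estimated correlation). The list of IL-10 and STAT3 induced genes also passed (14 of 21 higher, median 0.05, adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.39). The members of that list that rose were Socs3 and, with the block, Zfp36, which is also counted in the MAPK and mRNA decay list. The Kruppel-like factors and transcription repressors passed only with the block (9 of 14 higher, blocked adjusted p = 0.014, 0.04 with an estimated correlation).

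LPS plus IL-10 gave a larger set of risers between 10 and 30 min, led by Socs3. Socs3 rose from 541 ± 119 to 10873 ± 454 (n = 3; log2 fold change 4.31, SE 0.30, limma adjusted p = 2.17e-06). Sbno2, the co-repressor gene, rose from 460.2 ± 56.1 to 2150.1 ± 286 (log2 fold change 2.18, SE 0.22), and Etv3, an ETS-family repressor gene, rose from 579 ± 104 to 2331 ± 274 on its third-brightest probe set (1.99, SE 0.28). Cxcl2 (log2 fold change 2.33), Ier3 (1.94), Pde4b (1.87), Dusp1 (1.71) and Mt1, a metal-binding metallothionein gene (its dimmer probe set, from 75.4 ± 16.2 to 434 ± 43.4, 2.31), rose too. The brightest Mt1 probe set had 7919 ± 136 and 9297 ± 250 (0.23, adjusted p = 1.00, 0.857 with the block) and did not pass. In all, 12 probe sets of 8 genes rose and none fell without the block. With the block 53 probe sets of 35 genes rose and 8 fell, 2 of them named.

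Under LPS plus IL-10 the blocked calls at 30 min covered cytokines, chemokines and STAT3-regulated genes. Il1b rose from 217 ± 177 to 911 ± 379 (log2 fold change 2.14, blocked adjusted p = 0.00243), Ptgs2 by 1.96, Cxcl1 by 1.95, Tnfsf9 by 1.93 and Tnf by 1.15 (blocked adjusted p = 0.0454) on the log2 scale. The chemokine genes Ccl7 (1.70), Ccl4 (1.49), Ccl3 (1.45) and Ccl2 (1.02) rose, as did Tnfsf14 (2.25), a TNF-family cytokine gene with a dim signal of 50.3 ± 77.9 at 10 min. Gadd45g (1.80), the kinase gene Pim1 (1.01), the transcription factor gene Irf1 (1.06), Zfp36 (1.54), Nfkbiz (1.17), Csrnp1 (1.57), Ier2 (1.35), Ppp1r15a (1.08) and Tnfaip3 (0.68) rose, and the Il10 probe set rose by 1.62 (blocked adjusted p = 2.51e-05). With the block the brightest Etv3 probe set also rose (0.77, blocked adjusted p = 0.00257). The 2 named genes that fell were Nrp1, a semaphorin and VEGF co-receptor gene (not its brightest probe set, -1.13), and the noncoding Mir670hg (-1.29). Nfil3 (1.12, blocked adjusted p = 0.0766), Bcl3 (0.35), Stat3 (-0.02), Egr1 (1.70) and Nfkbia (0.10) did not pass. Without experiment 1, 2 or 3 the fit without a block called 4, 4 and 8 probe sets, and the blocked fit 18, 24 and 74.

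The gene lists moved in the same direction under LPS plus IL-10. Of the inflammatory cytokines and chemokines 13 of 14 were higher at 30 than at 10 min (median log2 fold change 1.47, camera adjusted p = 6e-27, 0.00043 with an estimated correlation), of the immediate early regulators 23 of 24 (median 0.49, adjusted p = 1.6e-20, 0.0063 with an estimated correlation) and of the MAPK and mRNA decay feedback genes 14 of 17 (median 0.35, adjusted p = 2e-10, 0.00043 with an estimated correlation). The IL-10 and STAT3 induced genes had 14 of 21 members higher (median 0.35, adjusted p = 1.8e-18, 0.0039 with an estimated correlation), of which 2 rose without the block and 6 with it, and 7 and 11 when adjusted over the list alone. That list holds Etv3 and Sbno2, which the study chose on these samples. The NF-kB pathway feedback list passed (14 of 15 higher, median 0.32, adjusted p = 1.5e-05), but not with an estimated correlation (adjusted p = 0.067; 0.0046 with the block as well). The Kruppel-like factors and transcription repressors again passed only with the block (8 of 14 higher, blocked adjusted p = 0.0083, 0.03 with an estimated correlation).

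The time courses share no arrays, and their risers at 30 min overlapped. All 5 probe sets that rose with LPS alone were among the 12 that rose with LPS plus IL-10, against 0.00221 expected for independent lists of these sizes. With the block, 24 probe sets of 16 genes rose in both, out of 29 and 53, against 0.0567 expected. The expected numbers hold only for independent lists, so they do not measure how unlikely this overlap is. The overlap says nothing about genes called in 1 time course only, whose difference is tested in the change of the IL-10 effect.

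**Figure D2:**
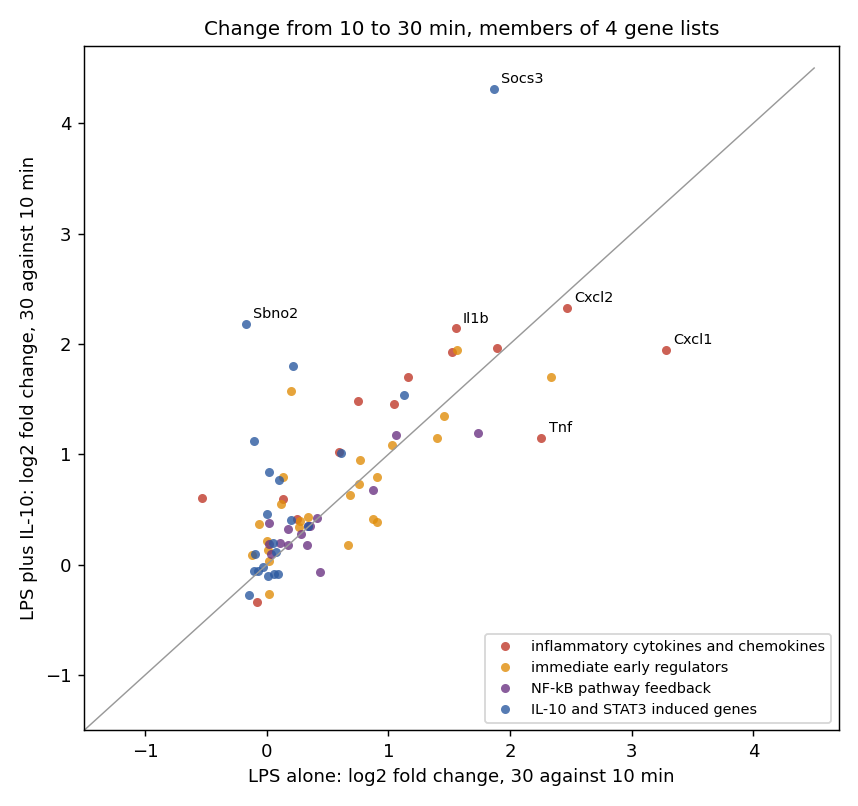
Log2 fold change from 10 to 30 min under LPS alone (horizontal axis) and LPS plus IL-10 (vertical axis) for the representative probe sets of 4 gene lists, with 1 point per gene, colours for the list and a diagonal marking equal changes. Socs3 (1.87 and 4.31) and Sbno2 (-0.17 and 2.18) lie above the diagonal, and Cxcl1 (3.28 and 1.95) and Tnf (2.26 and 1.15) below it.

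At 20 min fewer genes had moved. Under LPS plus IL-10, Socs3 rose from 541 ± 119 at 10 min to 5128 ± 707 at 20 min (n = 3; log2 fold change 3.22, SE 0.30, limma adjusted p = 0.000169) and Sbno2 from 460.2 ± 56.1 to 1384 ± 304 (1.54, SE 0.22, adjusted p = 0.0195). These were the 2 genes behind the 3 probe sets called, and none fell. With the block 9 probe sets of 7 genes rose, adding Cxcl2 (1.31), Etv3 on its third-brightest probe set (1.26), Ier3 (1.04), Dusp1 (1.01) and Zfp36 (0.82). Under LPS alone limma called no probe set without the block, with 899 probe sets at an unadjusted p under 0.05 (2487 with the block) where chance gives 1355.5. With the block 4 rose: Cxcl2 (1.69, blocked adjusted p = 0.00102), Dusp1 (1.33), Cxcl1 (1.76) and Socs3 on a probe set other than its brightest (1.57, blocked adjusted p = 0.0394). The brightest Socs3 probe set had a log2 fold change of 0.66 (SE 0.30) and did not pass. Without experiment 1, 2 or 3 the count under LPS plus IL-10 was 0, 1 and 1 (4, 5 and 10 with the block), and the blocked count under LPS alone was 3, 0 and 6.

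In the lists at 20 min, the inflammatory cytokines and chemokines passed under LPS plus IL-10 (14 of 14 higher, median log2 fold change 0.38, camera adjusted p = 0.00026) and under LPS alone (11 of 14, 0.44, adjusted p = 0.013), and neither held with an estimated correlation (adjusted p = 0.25 and 0.63). The immediate early regulators passed in both (20 of 24 higher in each, adjusted p = 0.00025 and 0.004), also not with an estimated correlation (adjusted p = 0.32 and 0.63). The MAPK and mRNA decay feedback genes passed in both (15 and 12 of 17 higher, adjusted p = 0.00026 and 0.013) and kept the call with an estimated correlation under LPS plus IL-10 alone (adjusted p = 0.045, against 0.26). The IL-10 and STAT3 induced genes passed under LPS plus IL-10 (13 of 21 higher, adjusted p = 0.00025; adjusted p = 0.25 with an estimated correlation). The NF-kB pathway feedback genes passed only with the block, in both (blocked adjusted p = 0.0088 with IL-10 and 0.03 without), and not with an estimated correlation (0.28 and 0.37). The Kruppel-like list passed with the block under LPS plus IL-10 (blocked adjusted p = 0.029, 0.095 with an estimated correlation). The LPS arrays of experiments 2 and 3 at 20 min, with lower quartiles of 38.6 and 34.0, enter every comparison of LPS alone at 20 min. Without both, the group is 1 array assumed to vary like the other groups, and the blocked fit called 1 riser, Dusp1, and 13 probe sets that fell.

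IL-10 had no detectable effect on any probe set at 10 min. Socs3 had a signal of 553 ± 138 with LPS and 541 ± 119 with LPS plus IL-10 (n = 3; log2 difference -0.02, 95% interval -0.65 to 0.60), and Sbno2 had 421 ± 126 and 460.2 ± 56.1 (log2 difference 0.15, -0.31 to 0.61). Etv3 differed by -0.16 on its brightest probe set, Tnf by 0.25, Cxcl1 by 0.52 and Nfil3 by -0.22 on the log2 scale. Limma called 0 of 27110 probe sets with or without the block, at a smallest adjusted p of 1.00 and 0.598. At an unadjusted p under 0.05 there were 309 probe sets without the block and 970 with it, where chance gives 1355.5. Without the block the differences between experiments count as spread, so the smaller number there is not evidence that IL-10 had no effect. None of the 19 lists passed.

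At 20 min IL-10 raised Socs3 and Sbno2. Socs3 had a signal of 884 ± 217 with LPS and 5128 ± 707 with LPS plus IL-10 (n = 3; log2 difference 2.53, SE 0.30, limma adjusted p = 0.00503), higher in 3 of 3 experiments. Sbno2 had 471 ± 29.7 and 1384 ± 304 (log2 difference 1.51, SE 0.22, adjusted p = 0.0394), also higher in 3 of 3. With the block 5 probe sets of 3 genes rose: these, another pair of Socs3 probe sets, and Etv3 on its third-brightest probe set (1.24, blocked adjusted p = 0.00181). The brightest Etv3 probe set differed by 0.24 (SE 0.24) and did not pass. The IL-10 and STAT3 induced genes passed (12 of 21 higher, median log2 difference 0.03, mean 0.27, camera adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.83). With the block 1, 5 and 6 probe sets were called without experiment 1, 2 or 3, and the 1 left without experiment 1 was none of these 5. The count without the block fell to 0 when any 1 experiment was left out, and to 1 and 0 without the LPS array of experiment 2 or 3. Without both of these arrays the LPS group is 1 array, and nothing passed without the block. In the blocked fit neither Etv3 nor the brightest Sbno2 probe set then passed. The log2 differences in that fit were 2.77 and 2.07 for 2 Socs3 probe sets. For another Sbno2 probe set, not called with all arrays, the difference was 1.70.

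At 30 min Sbno2 gave the strongest call. Its signal was 367 ± 67.3 with LPS and 2150.1 ± 286 with LPS plus IL-10 (n = 3; log2 difference 2.51, SE 0.22, limma adjusted p = 7.24e-05), with differences of 2.63, 2.45 and 2.44 in experiments 1, 2 and 3. Socs3 had 2196 ± 1134 and 10873 ± 454 (log2 difference 2.42, SE 0.30, adjusted p = 0.00464). A second Sbno2 probe set rose by 1.56 (adjusted p = 0.027). With the block 12 probe sets of 7 genes rose and none fell. The genes added were Etv3 (1.39 on its third-brightest probe set, blocked adjusted p = 0.000283, and 0.76 on another), Gadd45g (1.70, blocked adjusted p = 0.00261), Irf1 (1.03), Mt1 on its dimmer probe set (1.86, against 0.30 on the brightest, which did not pass) and Il10 (0.98, blocked adjusted p = 0.0233). The brightest Etv3 probe set differed by 0.50 (blocked adjusted p = 0.393), and the dimmest, with signals of 136 ± 36.5 and 155 ± 52.2, by 0.16 (SE 0.45), so the probe sets of Etv3 disagree on the call.

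Other known targets of IL-10 and STAT3 did not pass singly at 30 min. Nfil3 differed by 1.01 (95% interval 0.14 to 1.87), Zfp36 by 0.53, Bcl3 by 0.21 and the brightest probe set of Stat3 by 0.07 on the log2 scale. Another Stat3 probe set had 114 ± 23.4 with LPS and 468 ± 58.4 with LPS plus IL-10 (n = 3; log2 difference 1.91, SE 0.42, limma adjusted p = 0.627, 0.0984 with the block), so its probe sets differ. As a list the IL-10 and STAT3 induced genes were shifted upwards at 30 min (19 of 21 higher, median log2 difference 0.26, camera adjusted p = 4.2e-13, 0.039 with an estimated correlation). Of its members 2 rose over all probe sets and 3 with the block, and 3 and 6 when adjusted over the list alone, which is not independent evidence for Etv3 and Sbno2. Leaving out experiment 1, 2 or 3 left 0, 1 and 0 called probe sets without the block, and 1, 7 and 9 with it.

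**Figure D3:**
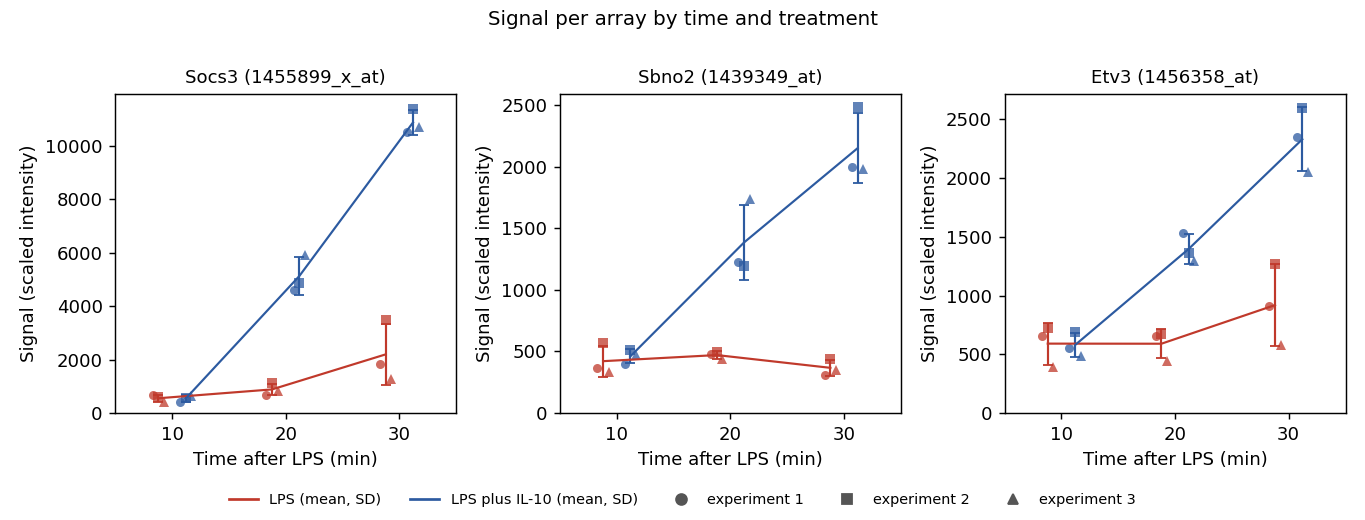
Scaled signal (vertical axis, linear) of Socs3, Sbno2 and the third-brightest Etv3 probe set against time after LPS in minutes, for LPS alone (red) and LPS plus IL-10 (blue), with 1 symbol per array shaped by experiment, lines joining group means and bars for SD (n = 3). The treatments overlap at 10 min, and at 30 min the LPS plus IL-10 arrays lie above all LPS arrays for each probe set shown.

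Inflammatory genes did not pass the test for an IL-10 difference at 30 min. Tnf had a signal of 6586 ± 3804 with LPS and 4338 ± 3338 with LPS plus IL-10 (n = 3; log2 difference -0.86, SE 1.09, adjusted p = 1.00, 0.944 with the block), and Cxcl1 had 4151 ± 2744 and 2547 ± 1791 (log2 difference -0.81, SE 0.56). These SEs are from the fit without the block and include the differences in level between experiments. The blocked fit removes those differences, and its SEs for both probe sets are smaller. They equal the blocked SEs given above for the rise of these probe sets from 10 to 30 min of LPS. Each mean difference is several times its blocked SE, but neither passed after adjustment. Not passing means no call after adjustment over all tested probe sets, and it does not show equal expression. The Tnf difference was -0.05, -1.02 and -1.51 in experiments 1, 2 and 3, and the Cxcl1 difference -0.24, -0.73 and -1.47. Ccl4 (log2 difference 0.82), Ccl3 (0.45), Il1b (0.30), Cxcl2 (-0.21) and Dusp1 (0.03) did not pass. The list of inflammatory cytokines and chemokines had 10 of 14 members higher and 4 lower with IL-10 (median log2 difference 0.34, camera adjusted p = 0.117). Immediate early regulators had 6 of 24 higher (adjusted p = 0.793), and the NF-kB and the MAPK and mRNA decay feedback lists had 9 of 15 and 8 of 17 higher (adjusted p = 0.793 for each).

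**Figure D4:**
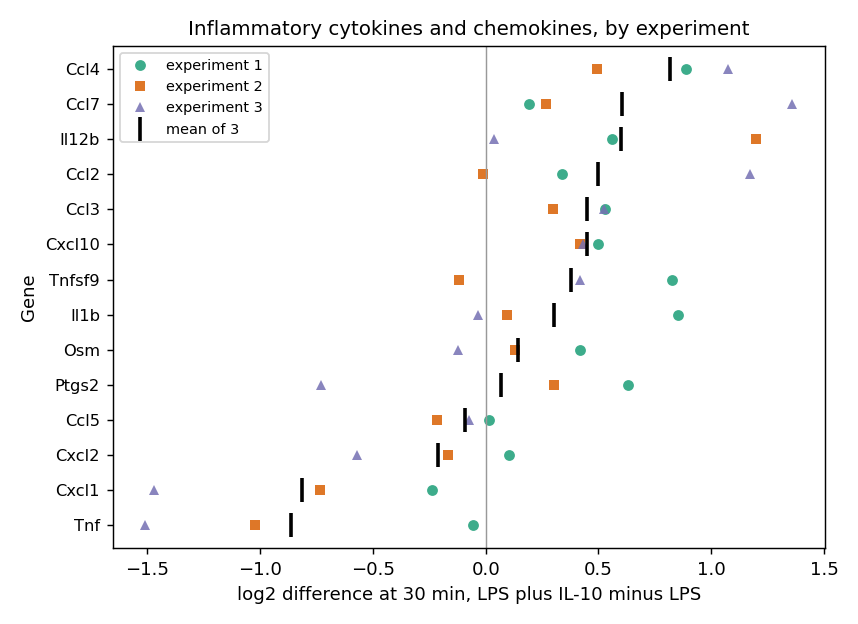
Log2 difference between LPS plus IL-10 and LPS at 30 min (horizontal axis) for the 14 measured inflammatory cytokines and chemokines (vertical axis), with symbols for the 3 experiments and a black bar for their mean. Tnf and Cxcl1 lie below 0 in each experiment and Ccl3 and Ccl4 above it, and no gene shown passed the test.

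Averaged over the 3 times, IL-10 raised Sbno2 and Socs3. Sbno2 rose by 1.39 (log2 difference, SE 0.13, n = 9 arrays per treatment, limma adjusted p = 0.000132), with 8 of 9 pairs of arrays higher. Socs3 rose by 1.64 (SE 0.17, adjusted p = 0.000503), with 7 of 9 pairs higher. Without the block 3 probe sets of 2 genes rose, and with it 9 probe sets of 5 genes, adding Gadd45g (0.85), Mt1 on its dimmer probe set (1.09, against 0.17 on the brightest) and Etv3 on its third-brightest probe set (0.88). The IL-10 and STAT3 induced genes passed (18 of 21 higher, median log2 difference 0.07, camera adjusted p = 2.9e-08), but not with an estimated correlation (adjusted p = 0.18; 0.002 with the block as well). The stromal and fibroblast markers, genes of cells that the cultures could also hold, were higher with IL-10 in 7 of 7 (median 0.17, adjusted p = 0.025), but not with an estimated correlation (adjusted p = 0.85; 0.031 with the block as well). Without experiment 1, 2 or 3 the count without the block was 0, 3 and 0, and the blocked count fell below 9 each time.

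The change of the IL-10 effect with time was tested as an interaction. From 10 to 30 min the effect on Sbno2 grew by 2.35 (log2 scale, SE 0.31, limma adjusted p = 0.0221), the 1 probe set called without the block. With the block 5 probe sets of 3 genes passed, adding Socs3 (2.45, blocked adjusted p = 0.0171) and Etv3 on its third-brightest probe set (1.39, blocked adjusted p = 0.0414). The same test compares the time courses, and Tnf (-1.11, SE 1.54), Cxcl1 (-1.33, SE 0.79), Gadd45g (1.58) and Il1b (0.59) did not pass it in either fit. The SEs of Tnf and Cxcl1 given here are from the fit without the block, which counts differences between experiments as spread. The blocked SEs are smaller, and both changes are several times as large as them. Neither change passed after adjustment over all tested probe sets. From 10 to 20 min no probe set passed without the block, with 556 at an unadjusted p under 0.05 (1725 with the block) where chance gives 1355.5. With the block 2 Socs3 probe sets passed, the brightest at 2.56 (blocked adjusted p = 0.0175), and Sbno2 differed by 1.35 (blocked adjusted p = 0.133). The 2 LPS arrays at 20 min that stood apart enter this comparison. The IL-10 and STAT3 induced genes passed from 10 to 30 min (17 of 21 higher, median 0.19, camera adjusted p = 3e-08), but not with an estimated correlation (adjusted p = 0.18; 0.0013 with the block as well). Without the block no call was left at 30 min when any 1 experiment was left out. Blocked, 0, 2 and 3 calls were left at 30 min without experiment 1, 2 or 3, and 0, 0 and 11 at 20 min.

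The remaining lists passed in none of the 10 comparisons, with or without the block. Without the block the smallest camera adjusted p was 0.117 for the macrophage markers (14 measured), 0.273 for granulocyte markers (10), 0.245 for dendritic cell markers (6), 0.155 for erythroid markers (2 measured of 8), 0.601 for B and T lymphocyte markers (3 measured of 12) and 0.749 for cell cycle genes (12). It was 0.329 for interferon response genes (16), 0.583 for TLR4 and IL-10 receptor signalling (19), 0.421 for heat shock and unfolded protein genes (12), 0.343 for serum response and cytoskeleton genes (13), 0.323 for housekeeping genes (11) and 0.114 for the sex-linked list, of which 1 gene was measured. The mean log2 signal of the macrophage markers lay between 13.39 and 13.52 over the 6 groups, and that of the stromal markers between 8.47 and 8.78.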

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

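The tests over other splits of the arrays and the test of background on 2 arrays were fixed before their results were seen. The tests of scaling and of single experiments, for Sbno2, Socs3 and Etv3, were chosen after.

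The IL-10 effect differed between times for 5 probe sets by the interaction test, 2 of them at both later times. From 10 to 20 min it grew by 2.56 (SE 0.42) for the brightest probe set of Socs3 and by 2.33 (SE 0.53) for another, past the threshold only with the replicate block (blocked adjusted p = 0.0175 for both). From 10 to 30 min it grew by 2.35 (SE 0.31) for the brightest probe set of Sbno2 in both fits (limma adjusted p = 0.0221, 0.000332 with the block). With the block alone it grew by 2.45 and 2.13 for the same Socs3 probe sets, by 1.39 for the third-brightest probe set of Etv3 and by 1.55 for another of Sbno2 (blocked adjusted p from 0.0171 to 0.0458).

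The larger effect on Sbno2, Socs3 and Etv3 at 30 than at 10 min was weighed against array scaling. A difference in scaling would shift all probe sets by a like amount. The median change of the IL-10 effect over all tested probe sets was -0.00585, against 1.39 for Etv3, the smallest of the 3 genes. The arrays arrived scaled to a like trimmed mean, which by itself keeps such a median small. The values show no common shift left over, but they cannot decide about the scaling itself. The changes in experiments 1, 2 and 3 were 2.51, 2.60 and 1.95 for Sbno2, 3.20, 1.75 and 2.38 for Socs3 and 1.59, 1.09 and 1.48 for Etv3. A test of these values against dependence on a single experiment, first set over the 3 genes and then gene by gene after its value was seen, was dropped. The genes had been picked by a fit that favours like changes in all experiments, so the test could decide nothing and that dependence stays open.

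Other splits of the same arrays were counted for each comparison. For the change of the effect from 10 to 20 min the real split gave 0 calls, which all 100 splits reach by construction, so that count tests nothing (the highest gave 2093). With the block 8 of 100 splits gave at least the 2 calls of the real one, and the highest gave 18. For the change from 10 to 30 min 10 of 100 splits gave at least the 1 call of the real one, and the highest gave 3. With the block 7 of 100 gave at least the real 5, and the highest gave 7. Of the 9 other splits as large without the block 8 keep the real grouping at 1 of the times, so they carry part of the real effect. Of the splits that part all pairs, 2 of 15 to 20 min and 3 of 17 to 30 min were as large with the block. With that limit, these splits leave open whether chance gave the blocked count to 20 min or the counts to 30 min. For the average over times 3 of 100 splits gave at least the 3 calls of the real one, but 93 of the 100 leave some same-numbered arrays of a time in 1 group. Of the 7 that part all pairs the real one alone gave any call (3, and 9 with the block), and 7 are too few for a share under 0.05. The highest of the others gave 2901 calls without the block, which points to a structure of the samples, and the highest with the block gave 10.

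The comparisons of 3 against 3 arrays have 10 splits each, too few for a share under 0.05. The real count and the highest of the others were 0 and 0 for IL-10 at 10 min (all 10 splits as large, which a count of 0 forces), 2 and 1 at 20 min (1 split, the real one) and 3 and 0 at 30 min (1). They were 0 and 0 for LPS alone from 10 to 20 min (again all 10), 5 and 0 from 10 to 30 min (1), and 3 and 0 and 12 and 0 for LPS plus IL-10 over the same intervals (1 each). With the block, IL-10 at 20 min had 5 calls, and 3 of 10 splits, the real one included, gave at least as many. The others among these gave 110 and 13. Both leave arrays of the same experiment in 1 group, and the other splits that part all pairs gave 0.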

How the results depend on the processing

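Settings that leave out the LPS arrays of experiment 2 or 3 at 20 min, or leave arrays out of the blocked fit, were chosen after seeing the data, and the others were planned. No named gene reversed its direction past the threshold under any of them but those that leave arrays out of the blocked fit, where only calls were counted. Lists were run with an estimated correlation, the block, quantile normalisation, the mean of all probe sets of a gene and without each experiment. None reversed past the threshold there. The cause of a moved count was not tested, except that fits on fewer arrays have fewer residual degrees of freedom. IL-10 at 10 min gave 0 calls under every setting run. Of 23 calls of named genes, 20 were kept with quantile normalisation, 21 and 22 with pseudocounts of 1 and 64, 23 without a filter, 23 with the replicate block (which added 53), 18 without the intensity trend and 5, 6 and 8 without experiment 1, 2 or 3. Without the LPS array of experiment 2, of experiment 3 or of both at 20 min 20, 19 and 17 were kept. A fit on only the arrays compared kept 7 of 21, and the stricter filter 22 of 22. The median of all probe sets stayed between -0.0308 and 0.0207 with the deposited scaling and with quantile normalisation. The deposited table gives no background measure, so how far dim signals lie above background limits the low end.

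Called probe sets without the block were, in order, 2 for IL-10 at 20 min, 3 at 30 min and 3 on average, 0 and 5 for LPS at 20 and 30 against 10 min, 3 and 12 for LPS plus IL-10, and 0 and 1 for the change of the effect from 10 to 20 and to 30 min. With the replicate block they were 5, 12, 9, 4, 30, 9, 61, 2 and 5, and the block changed no call at 10 min. Quantile normalisation moved IL-10 at 20 min to 1 and LPS at 30 min to 3, and a pseudocount of 1 moved LPS at 30 min to 3. Without the intensity trend IL-10 at 20 min had 1, LPS at 30 min 2 and the change to 30 min 0. A fit on only the arrays compared gave 0 for IL-10 at 20 min, 1 at 30 min, 0 for LPS at 30 min, 1 and 7 for LPS plus IL-10 and 0 for the change to 30 min. For the average it is the fit on all arrays, so it was not run.

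Leaving out 1 experiment at a time gave 0 to 0 calls for IL-10 at 20 min, 0 to 1 at 30 min, 0 to 3 on average, 0 to 2 for LPS at 30 min, 0 to 1 and 4 to 8 for LPS plus IL-10 at 20 and 30 min, and 0 to 0 for the change to 30 min. In the blocked fit the ranges were 1 to 6 (the 1 being a new call), 1 to 9 and 2 to 6 for IL-10 at 20 and 30 min and on average, 0 to 6 and 8 to 32 for LPS, 4 to 10 and 18 to 74 for LPS plus IL-10, and 0 to 11 and 0 to 3 for the changes.

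Without the LPS array of experiment 2 at 20 min there was 1 call for IL-10 at 20 min, 5 at 30 min, 6 on average and 3 for LPS at 30 min. Without that of experiment 3 there were 0 for IL-10 at 20 min and 3 for LPS at 30 min. Without both there were 0 for IL-10 at 20 min, 6 at 30 min, 3 for LPS at 30 min and 0 for the change to 30 min. In the blocked fit without both there were 15 for IL-10 at 20 min, 14 for LPS at 20 min and 7 for the change to 20 min. The LPS group at 20 min is then the 1 array of experiment 1, assumed to vary like the other groups.

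Of 22 list calls, 10 held with an estimated correlation, 22 with the block (which added 5), 21 with quantile normalisation, 21 with the mean of all probe sets of a gene and 18, 19 and 20 without experiment 1, 2 or 3.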

Other observations

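The comparison of experiments, the tests of an earlier LPS stage and of scaling, and the calls without 2 arrays were chosen after the data were seen. The test of background was fixed before.

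The 3 experiments differed in more probe sets than any comparison of treatment or time called. These tests also use more arrays than the comparisons of 3 against 3. The cell cycle list was higher in experiment 1 than in the mean of experiments 2 and 3 (12 of 12 members past limma's adjusted threshold, median log2 difference 0.91, camera adjusted p = 2.5e-12, 0.009 with an estimated correlation). It was also higher in experiment 3 than in experiment 2 (8 of 12 higher and 3 lower, median 1.02, adjusted p = 0.00064), though not with an estimated correlation (adjusted p = 0.09), and the cyclin gene Ccnb2 had mean signals of 3568, 978 and 4907 in experiments 1, 2 and 3. The immediate early regulators were higher in experiment 1 (15 of 24, adjusted p = 0.00043), though not with an estimated correlation (adjusted p = 0.099). The chemokine gene Ccl5 had a mean signal of 149 ± 19.2 (SD, n = 6 arrays) in experiment 1, 7098 ± 728 in experiment 2 and 1128 ± 235 in experiment 3. The acute-phase gene Saa3 had 1213 ± 143, 10667 ± 945 and 14877 ± 2202, and the complement gene Cfb 52.8 ± 16.6, 992 ± 133 and 330.1 ± 56.6. The monocyte chemokine receptor gene Ccr2 went the other way, with 1352 ± 159, 175 ± 70.3 and 329 ± 97.9. These genes were picked for a mean log2 signal above 8 and the same sign in 6 of 6 groups, so that agreement is no added evidence. The housekeeping list as a whole passed in neither comparison of experiments. Its median log2 difference was -0.061 for experiment 1 (camera adjusted p = 0.355) and -0.0011 for experiment 3 against 2 (adjusted p = 0.544). Picked from its largest differences, a Tfrc probe set had 1671 ± 372, 224 ± 68.8 and 330 ± 57.5. A Ywhaz probe set went the other way, with 768 ± 104, 2544 ± 709 and 5579 ± 3136. In all, 5738 probe sets were higher and 6256 lower in experiment 1, but the 6 arrays of an experiment share 1 preparation of cells, so these tests do not measure the spread between preparations. Arrays of an experiment may also share RNA and array work, and such technical differences cannot be told apart from those of the cells.

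Experiment 3 differed from experiment 2 in 3188 higher and 3348 lower probe sets. The fractalkine receptor gene Cx3cr1 had a mean signal of 348 ± 119 in experiment 2 and 3494 ± 440 in experiment 3 (SD, n = 6), and Acod1, the itaconate-producing enzyme gene, had 2698 ± 556 and 13722 ± 1517. Tnf had 3927 ± 3064 and 806 ± 770, the IL-1 receptor antagonist gene Il1rn 3539 ± 326 and 608 ± 161, and Id3, a repressor of helix-loop-helix factors, 6070.1 ± 695 and 1075 ± 478. The Kruppel-like and repressor list was lower in experiment 3 (9 of 14 past the threshold, camera adjusted p = 0.00064, 0.035 with an estimated correlation), and so was the inflammatory list (8 of 14, adjusted p = 0.00064), though not with an estimated correlation (adjusted p = 0.22). Lower too, but not with an estimated correlation, were the immediate early regulators (adjusted p = 0.002; 0.09), the IL-10 and STAT3 induced genes (0.0047; 0.077) and the granulocyte markers (0.023; 0.2). The B and T lymphocyte markers, 3 measured, were higher (adjusted p = 0.013; 0.09 with an estimated correlation).

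The LPS arrays of experiments 2 and 3 at 20 min stood apart in their low signals. Their second percentiles of signal were 7.9 and 5.07, against 2.2 to 3.4 on the other 16 arrays, and the array of experiment 3 had the brightest spike-in controls (7364, against 1817 to 4497 on those 16). A raised background would lift control probe sets with no target, but only 2 dim control probe sets qualified, fewer than the 5 set beforehand as the minimum. Their median signal was 33.7 on the array of experiment 2 and 20.3 on that of experiment 3, against 2.25 to 24.7 on the others, so raised background cannot be told apart from other causes for either. No biological explanation was tested, and the LPS array of experiment 1 at the same time had a lower quartile of 23.0, inside the range of the others.

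New blocked calls in comparisons with LPS alone at 20 min, once these 2 arrays are left out, rest on the 1 LPS array left at that time. Ropn1l differed by 2.65 between treatments at 20 min and by -2.73 between 20 and 10 min of LPS on the log2 scale, and Zmynd15 by 2.55 and -2.68. At 30 min, where both groups keep their 3 arrays, the same setting added Stat3 on a probe set other than its brightest (log2 difference 1.91, adjusted p = 0.00233), while its brightest probe set differed by 0.07 in the fit with all arrays, and the cause of the added call was not tested.

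Tnf and Cxcl1 were lower with IL-10 at 30 min in experiments 2 and 3 (Tnf -1.02 and -1.51, Cxcl1 -0.73 and -1.47), and closer to equal in experiment 1 (-0.05 and -0.24), without passing the test. Scaling would move all probe sets, and their median difference in experiment 2 was -0.00649, against -0.73 for the smaller of the 4 differences. The arrays arrived scaled to a like trimmed mean, which keeps such a median small, so this cannot decide about scaling. If IL-10 held the cells at an earlier stage of the LPS response, the genes that rose in both time courses would mostly be lower with IL-10. Of 16 such genes 7 were higher in experiment 3, 6 in experiment 2 and 13 in experiment 1, and the bound set for excluding it was 8, so this stays open. The 16 were picked in part by their rise on the same LPS plus IL-10 arrays, which favours genes high with IL-10. They also include Socs3 and the 2 genes to be explained, Tnf and Cxcl1. Whether the effect of IL-10 on these genes differs between preparations was not tested here.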
